A study of Mus musculus with 19 samples.

How the data were processed

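RNA of Sec24d-knockout mouse embryonic fibroblasts had been extracted with TRIzol, reverse transcribed and sequenced in 19 libraries. The series text does not say whether libraries were stranded or poly(A)-selected, so reads of overlapping genes on opposite strands cannot be told apart. The submitters' notes name Trimmomatic 0.27, FastQC 0.10.1, TopHat2 2.0.8 and Partek 6.6 without stating their order, and give the builds hg19 and GRCh37, which are human. The gene IDs are mouse: 19666 of 19716 were found in GENCODE M21 (GRCm38), and 99.0% of these had identical start and end positions, so coordinates are given in GRCm38. The sources used here name no read counter, size factor method or testing tool, and do not say how reads that map to several places were counted.

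The signal values deposited by the authors are read counts divided by 1 factor per library and rounded to 2 decimals. Dividing each library by its smallest step (0.736 to 1.638 per read) gave whole reads for 100% of values within 0.0055, with 9101855 to 19709672 reads per library. At this depth 1 read corresponds to about 1 normalised count, so genes with means of a few counts rest on few reads. Reads carry no molecular identifiers, so counting error covers only part of their uncertainty. The log2 fold changes in the authors' table and the adjusted p-values deposited beside them were used only for comparison; they are the authors' p-value columns and were not recomputed. No gene in the table had a summed normalised count below 10.01 or fewer than 2 libraries above 0, and none of the per-sample columns was left out.

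Groups were taken from the sample labels. All 19 libraries were fitted together with 4 group means in limma 3.58.1 (R 4.3.3), with an intensity trend, on log2 of the normalised count plus 1. Genes with a value of at least 1 in at least 4 libraries were kept, which left 19635 and removed 81. The pseudocount makes log2 fold changes of genes with few counts smaller than the ratio of their means. Tests were two-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, with no minimum fold change. The comparisons were the Sec24B knockdown minus 50 nM scrambled siRNA, the triple knockdown minus 150 nM scrambled siRNA, 150 minus 50 nM scrambled siRNA, and the difference between the knockdown effects. These tests, the gene lists and the rule for named genes were fixed before the data were examined. The plan gave edgeR for raw counts and limma for normalised values; the values are scaled counts, so the limma branch was used, and edgeR on the recovered reads is among the alternatives.

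Of 43 gene lists fixed, the 40 with at least 5 measured genes were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of each comparison. Camera compares a list with all other genes. Each test was repeated with the correlation estimated from the data. Member counts are given at an adjusted p of 0.05 over all genes and adjusted over the list alone.

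The named genes were Sec24a to Sec24d, then for each knockdown the 8 largest rises and 8 largest falls among genes that passed. These needed a mean of at least 1 in the higher group, libraries of the groups compared that did not overlap, and a symbol that is not a clone or predicted name. For each list that passed in a knockdown up to 3 members with the smallest adjusted p were named, and for lists that did not pass at most 2; some members that this rule picks are not described here. For the scrambled doses and the difference of effects the 5 largest per direction were named. Genes shown by this rule for 1 comparison are in places given for another as well.

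The same fit was tested on simulated data in which 200 genes with a mean of at least 20 were changed. It recovered 55 of 62 genes changed by 1.5-fold and 69 of 69 changed by 2-fold in the Sec24B design, and called 6 of 19302 unchanged genes. The triple knockdown design gave 64 of 69, 66 of 66 and 8 of 19251. The simulation had independent genes, no outlying library and few changed genes, so these rates need not hold for the real data. Alternatives covered the pseudocount, the low-value filter, rescaling, the libraries in the fit, a replicate block, pooled scrambled controls, leaving out each replicate or 2 libraries at once, the fry test for lists, and, on the recovered reads, edgeR 4.0.16, DESeq2 1.42.0 and limma-voom. Searches of 3' UTRs for 7-base words used GENCODE M21 transcripts of coding genes with a mean of at least 50, with 3' UTR length, GC content and expression as covariates. Figures were drawn with matplotlib 3.10.9, and values handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.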

Results

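RNA was sequenced from mouse embryonic fibroblasts that lack a working Sec24d gene and were transfected with further siRNAs. SEC24 proteins are the cargo-binding subunits of COPII, the coat that forms transport vesicles on the endoplasmic reticulum (ER), and their paralogs are SEC24A, SEC24B, SEC24C and SEC24D. The 19 libraries fell into 4 groups. All are labelled 48 h, while the protocol text has the medium changed on the morning after transfection and RNA collected a day later. The groups were 4 libraries with 50 nM scrambled siRNA, 5 with Sec24b siRNA (Sec24B knockdown), 5 with 150 nM scrambled siRNA, and 5 with siRNAs against Sec24a, Sec24b and Sec24c together (triple knockdown). The labels give 50 nM for the SEC24 siRNAs without saying whether that is each or in total. The pairing of the triple knockdown with the 150 nM control was read from the doses and library names. The reads per library, recovered from the deposited values, numbered 12627947 to 19709672 with 50 nM scrambled siRNA and 11490390 to 16927701 in the Sec24B knockdown. They numbered 9101855 to 15719649 with 150 nM scrambled siRNA and 12919930 to 17352612 in the triple knockdown. The labels do not say that replicates were separate cultures; if they were not, the p-values measure only the spread between these samples. Levels are normalised read counts, as mean ± SD over these libraries, and log2 fold changes carry the standard error of the fit.

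The siRNAs lowered the transcripts they were directed against. Sec24b (ENSMUSG00000001052, GRCm38 chromosome 3, 129982759 to 130061553) fell from 1114 ± 76.7 (n = 4) to 479 ± 16.9 (n = 5) in the Sec24B knockdown, a log2 fold change of -1.21 ± 0.10 (limma adjusted p = 2.01e-08). In the triple knockdown it fell from 1222 ± 39.0 to 509 ± 105 (n = 5 each), a log2 fold change of -1.29 ± 0.10 (adjusted p = 1.31e-10), and the 2 effects on Sec24b did not differ detectably (difference -0.07 ± 0.14, adjusted p = 0.788). Sec24c (ENSMUSG00000039367, chromosome 14, 20674308 to 20694852) was the most reduced of the targets in the triple knockdown, from 2795 ± 95.1 to 809 ± 44.0 (log2 fold change -1.79 ± 0.05, adjusted p = 1.21e-17). Sec24a (ENSMUSG00000036391, chromosome 11, 51692264 to 51763634) fell there from 800 ± 57.0 to 487 ± 130 (log2 fold change -0.76 ± 0.13, adjusted p = 4.94e-05). Without triple knockdown replicates 1 and 5, which held the least Sec24a (299 and 403, against 572 to 583 in the others), the log2 fold change was -0.47. Neither Sec24a nor Sec24c passed the test in the Sec24B knockdown, with log2 fold changes of -0.19 ± 0.14 (adjusted p = 0.422) and -0.00 ± 0.06 (adjusted p = 0.988). Transcripts of the knocked-out Sec24d (ENSMUSG00000039234, chromosome 3, 123267455 to 123365641) were still counted in every group, at 428 ± 35.5 and 465 ± 26.1 in the 50 and 150 nM controls. They stood at 451 ± 62.4 in the Sec24B knockdown and 452 ± 136 in the triple knockdown, with neither passing the test (adjusted p = 0.866 and 0.651). The deleted part of Sec24d is not given in the labels, so this level says nothing for or against the knockout.

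**Figure D1:**
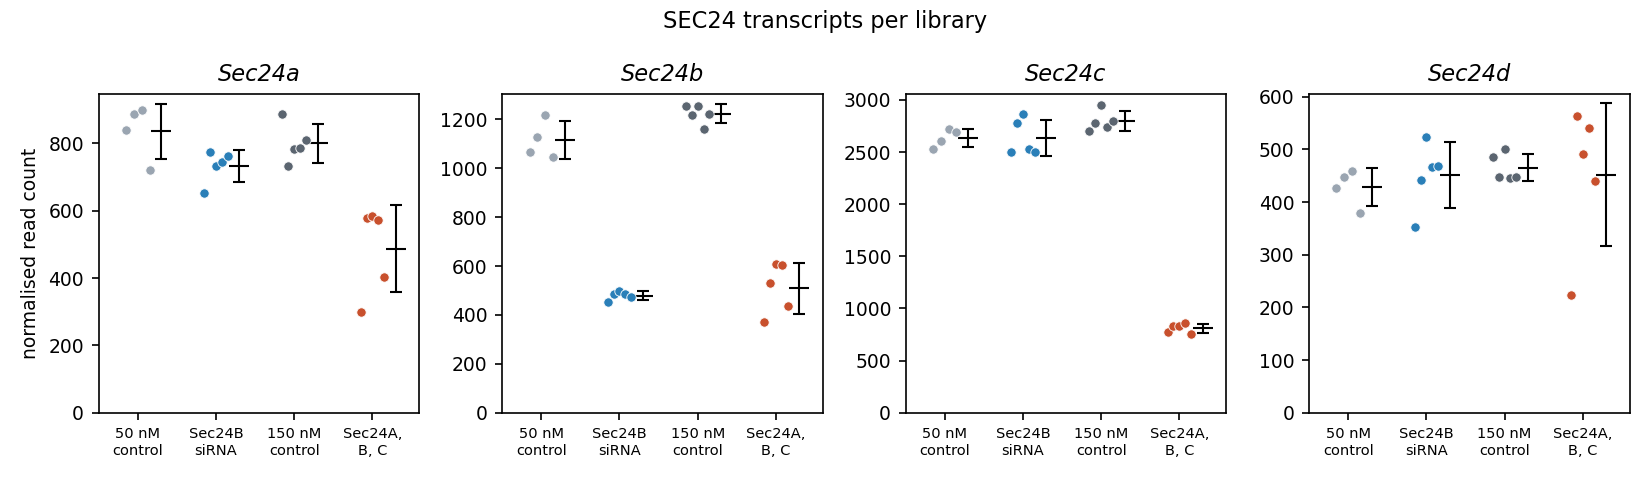
Normalised read counts of Sec24a, Sec24b, Sec24c and Sec24d (vertical axes) in each library of the 4 groups (horizontal axes), where points are libraries and the black bars beside them the mean and SD. All 5 Sec24B knockdown libraries lie between 454 and 498 for Sec24b, below every scrambled library, and triple knockdown replicate 1 is the lowest of its group for Sec24a (299), Sec24b (369) and Sec24d (223).

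The comparison of the Sec24B knockdown with 50 nM scrambled siRNA asks what loss of SEC24B changes in cells already without SEC24D. As lists, interferon-stimulated genes passed as higher, and glycolysis and hypoxia genes and TGF-beta targets as lower. None of these 3 calls held with an estimated correlation between genes. Among the 37 measured interferon-stimulated genes, 21 rose and 0 fell (27 and 1 adjusted over the list alone), with a median log2 fold change of 0.42. They included Rsad2, an antiviral radical SAM enzyme (241 ± 13.3 to 521 ± 98.7, log2 fold change 1.09 ± 0.14), Cmpk2, a mitochondrial nucleotide kinase (0.91 ± 0.10), and Oas2, a sensor of double-stranded RNA (0.85 ± 0.10). Their adjusted p-values were 7.17e-06, 4.50e-07 and 3.33e-06. Of the 21 genes of glycolysis and hypoxia, 14 fell and 2 rose (16 and 2 adjusted over the list alone; median -0.30), among them the glycolytic enzymes Pgam1 (-0.58 ± 0.05) and Hk2 (-0.52 ± 0.06) and the mitophagy receptor Bnip3 (-0.72 ± 0.08). In the TGF-beta list 5 of 11 genes fell and 1 rose (the same counts adjusted over the list alone; median -0.07). The negative feedback genes Skil (-0.93 ± 0.10) and Pmepa1 (-0.77 ± 0.08) fell there. The camera adjusted p-values of the 3 lists were 5.97e-16, 4.49e-09 and 0.000939, and none held when the correlation between genes was estimated (adjusted p = 0.274, 0.105 and 0.232 with an estimated correlation).

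Heat shock genes fell in the Sec24B knockdown, 7 of 13 with 0 higher (9 adjusted over the list alone; median -0.27), including the cytosolic chaperones Hspa4 (-0.35 ± 0.05) and Hsph1 (-0.34 ± 0.06) and the mitochondrial chaperonin Hspd1 (-0.37 ± 0.06). This list alone of the 13 that passed (camera adjusted p = 6.24e-05) also held with an estimated correlation (adjusted p = 0.0107). Without its mitochondrial members Hspd1 and Hspe1, left out after the data were seen, 6 of 11 fell and 0 rose (camera adjusted p = 0.000732; adjusted p = 0.0413 with an estimated correlation). DNA replication genes fell as well, 7 of 20 with 0 higher (8 adjusted over the list alone; median -0.08), led by the helicase subunit Mcm4 (-0.68 ± 0.06) and the cyclin Ccne1 (-0.70 ± 0.10). Mitosis genes rose, 11 of 26 with 0 lower (15 adjusted over the list alone; median 0.18), with Cdc20, an activator of the anaphase-promoting complex, at 0.48 ± 0.08 and the kinase Aurka at 0.29 ± 0.06. The camera adjusted p-values were 8.11e-05 and 5.38e-05 (adjusted p = 0.232 and 0.491 with an estimated correlation). With both scrambled groups pooled as 1 control, Cdc20 (log2 fold change 0.22) and Aurka (0.12) no longer passed.

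Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, rose modestly in the Sec24B knockdown: 12 of 28 were higher and 1 lower (15 and 1 adjusted over the list alone; median 0.17). The amino acid transporter Slc7a5 rose by 0.75 ± 0.07, the mTORC1 inhibitor Sesn2 by 0.48 ± 0.07 and the lipoprotein receptor Vldlr by 0.60 ± 0.09. Aminoacyl-tRNA synthetases, which charge tRNAs and are ATF4 targets in part, had 4 of 13 higher and 0 lower (6 adjusted over the list alone; median 0.14), such as Aars at 0.24 ± 0.06. Called members that lost their calls with 1 library left out were Sars (0.25 ± 0.07), without 50 nM scrambled replicate 3 (0.23), and Iars (0.20 ± 0.06). Iars lost its call without 50 nM scrambled replicate 1 (0.19) or 4 (0.17) or Sec24B replicate 2 (0.17), 3 (0.20) or 5 (0.20). Golgi glycosylation genes had 7 of 24 lower and 1 higher (8 and 1 adjusted over the list alone; median -0.07), with the chondroitin sulfotransferase Chst11 at -0.66 ± 0.09 and the heparan sulfate polymerase Ext1 at -0.39 ± 0.06. The camera adjusted p-values were 7.84e-06, 0.000919 and 0.00179 (adjusted p = 0.232, 0.491 and 0.340 with an estimated correlation). In the cholesterol synthesis list 8 of 25 genes fell and 3 rose (the same counts adjusted over the list alone; median -0.07). Its member Sc5d, a sterol desaturase, fell by 0.60 ± 0.07 on the log2 scale. Its camera adjusted p of 0.0132 (adjusted p = 0.586 with an estimated correlation) became 0.0743 without 50 nM scrambled replicate 4.

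Mitochondrially encoded genes passed as lower (median -0.19, camera adjusted p = 0.000873; adjusted p = 0.491 with an estimated correlation). Of these 13 genes 1 fell and 0 rose (the same counts adjusted over the list alone). That gene, mt-Nd6, went from 308 to 148 (-1.09 ± 0.28, adjusted p = 0.00908) and lost its call without 50 nM scrambled replicate 1 (-0.90). The gene mt-Nd1 (-0.26) did not pass in the main fit but passed in several other settings. These included leaving out 50 nM scrambled replicate 4 (-0.32) or Sec24B replicate 1 (-0.33), the stricter filter and only the groups compared in the fit. On the recovered reads it passed with edgeR (-0.26), DESeq2 (-0.26) and limma-voom (-0.27), but not with upper-quartile factors. It did not pass with the scrambled groups pooled. Among p53 targets 5 of 19 rose and 1 fell (6 and 2 adjusted over the list alone), including the stress gene Sesn1 (0.50) and the death receptor Fas (0.66). In the lysosome list 7 of 28 rose and 2 fell (the same counts adjusted over the list alone), including the protease Ctsd (0.54). The p53 and lysosome lists passed with camera adjusted p-values of 0.0406 and 0.0475 (adjusted p = 0.380 and 0.586 with an estimated correlation). The p53 call ended without 50 nM scrambled replicate 3 (0.0590) or 4 (0.0700) or Sec24B replicate 1 (0.0808) or 4 (0.0513), and with the stricter filter (0.0552). The lysosome call ended without 50 nM scrambled replicate 1 (0.0683), 2 (0.0681) or 3 (0.0741) or Sec24B replicate 1 (0.0983) or 2 (0.0524), with the stricter filter (0.0552) and with the replicate number as a block (0.0609).

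The lists of the COPII coat, ER export cargo receptors and planar cell polarity did not pass in the Sec24B knockdown. COPII coat and ER exit site genes had 1 higher and 4 lower of 17 (2 and 4 adjusted over the list alone; camera adjusted p = 0.531), with the GTPase Sar1a at -0.26 ± 0.05 (adjusted p = 0.00128). ER export cargo receptors had 4 higher and 5 lower of 22 (4 and 6 adjusted over the list alone; camera adjusted p = 0.538), with the p24 protein Tmed5 at -0.63 ± 0.09 (adjusted p = 3.27e-05). Planar cell polarity genes, whose member VANGL2 is a known SEC24B cargo, had 3 higher and 3 lower of 11 (4 and 5 adjusted over the list alone; camera adjusted p = 0.994). Of these Fzd6, a Frizzled receptor, stood at -0.84 ± 0.12 (adjusted p = 2.03e-05) and the receptor tyrosine kinase-like Ptk7 at 0.42 ± 0.06 (adjusted p = 6.71e-05). In the collagen modification list, which did not pass either (4 higher and 5 lower of 28, 6 and 5 adjusted over the list alone; camera adjusted p = 0.994), the collagen cross-linking enzyme Lox fell from 11784 ± 396 to 5357 ± 376 (-1.14 ± 0.09, adjusted p = 9.03e-09).

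Single genes with the largest changes in the Sec24B knockdown were mostly expressed at low levels. The matrix proteoglycan Prelp rose from 3.75 ± 1.86 to 21.8 ± 2.88 (log2 fold change 2.36 ± 0.39, adjusted p = 0.000121) and the MHC class I gene H2-Q4 from 45.3 ± 14.5 to 199 ± 33.6 (2.15 ± 0.35, adjusted p = 0.000104). H2-Q4 has close paralogs, and how reads shared with them were counted is not given. Fndc7 (2.33 ± 0.37), Stab2 (2.15 ± 0.52), Rcsd1 (2.12 ± 0.45), Hgfac (2.01 ± 0.47) and Ggt5 (1.95 ± 0.48) rose from control means of 1.15 to 2.83. Stab2 and Ggt5 did not pass with a pseudocount of 0.1 (2.80 and 2.42). Ankrd7, listed at 0 in all 4 control libraries, averaged 3.33 ± 2.52 after knockdown (adjusted p = 0.00655). Ndnf, a secreted neurotrophic factor, fell from 223 ± 30.6 to 70.4 ± 4.5 (-1.64 ± 0.15, adjusted p = 3.63e-08). The organic anion transporters Slco1a6 (35.4 ± 8.87 to 6.69 ± 3.57, -2.32 ± 0.30) and Slco1a5 (53.9 ± 5.44 to 18 ± 2.8, -1.53 ± 0.19) fell with adjusted p-values of 6.07e-06 and 4.35e-06. Being paralogs, they are open to shared reads. Prss46 (-2.08 ± 0.30) and Prss22 (-1.66 ± 0.30), serine proteases, and Hbb-bh1 (-1.97 ± 0.40), an embryonic globin, fell from control means of 20.1, 26.9 and 6.43. Septin2 (-1.67 ± 0.51, adjusted p = 0.0282) and Cstl1, listed at 0 in all 5 Sec24B libraries (control mean 2.78, adjusted p = 0.0206), lost their calls with 1 library left out. This held for Septin2 without 50 nM scrambled replicate 1 (-1.20) or 4 (-1.65) or Sec24B replicate 2 (-1.34) or 5 (-1.56), and for Cstl1 without 50 nM scrambled replicate 3 (-1.72) or 4 (-1.76).

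Over all 19635 genes tested, 2868 (14.6%) differed between the Sec24B knockdown and 50 nM scrambled siRNA at an adjusted p of 0.05, 1478 higher and 1390 lower. With both scrambled groups pooled as 1 control the count was 4470, of which 2488 were among the 2868 in the same direction. For 2500 of the 2868 genes every knockdown library lay beyond every control library. Chance gives this for 1.59% of unselected genes, but called genes were picked from the same libraries, so the shares are not comparable. A log2 fold change of at least 1 was reached by 226 of the higher and 87 of the lower genes.

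The comparison of the triple knockdown with 150 nM scrambled siRNA asks what cells short of SEC24A, SEC24B, SEC24C and SEC24D together change. The targets of ATF4 and CHOP rose together: 27 of 28 were higher and 0 lower (27 adjusted over the list alone), with a median log2 fold change of 1.36. Trib3, a pseudokinase that feeds back on ATF4, rose from 669 ± 133 to 3238 ± 349 (2.29 ± 0.10, adjusted p = 5.90e-15). Chac1, which degrades glutathione, rose from 441 ± 50.2 to 1790 ± 244 (2.02 ± 0.08, adjusted p = 5.31e-15), and Gpt2, a mitochondrial alanine transaminase, from 611 ± 65.7 to 2108 ± 116 (1.79 ± 0.07, adjusted p = 4.61e-16). Aminoacyl-tRNA synthetases followed, 12 of 13 higher and 0 lower (13 adjusted over the list alone; median 0.87), including Wars (1.3 ± 0.05), Nars (1.05 ± 0.06) and Lars (0.94 ± 0.05). Camera adjusted p-values were 3.91e-35 and 8.71e-20, and both lists held with an estimated correlation (adjusted p = 0.000688 and 0.0127).

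Sterol genes fell in the triple knockdown without exception: 25 of 25 in the cholesterol synthesis list were lower (25 adjusted over the list alone), with a median of -1.08 (camera adjusted p = 1.44e-29; adjusted p = 0.00674 with an estimated correlation). Fatty acid synthesis genes had 9 of 15 lower and 3 higher (10 and 4 adjusted over the list alone; median -0.44; camera adjusted p = 0.000160). The desaturases Scd1 (-1.35 ± 0.08) and Scd2 (-0.88 ± 0.07) and the acyl-CoA synthetase Acsl3 (-1.08 ± 0.07) were among those that fell, and the list did not pass with an estimated correlation (adjusted p = 0.0665).

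**Figure D2:**
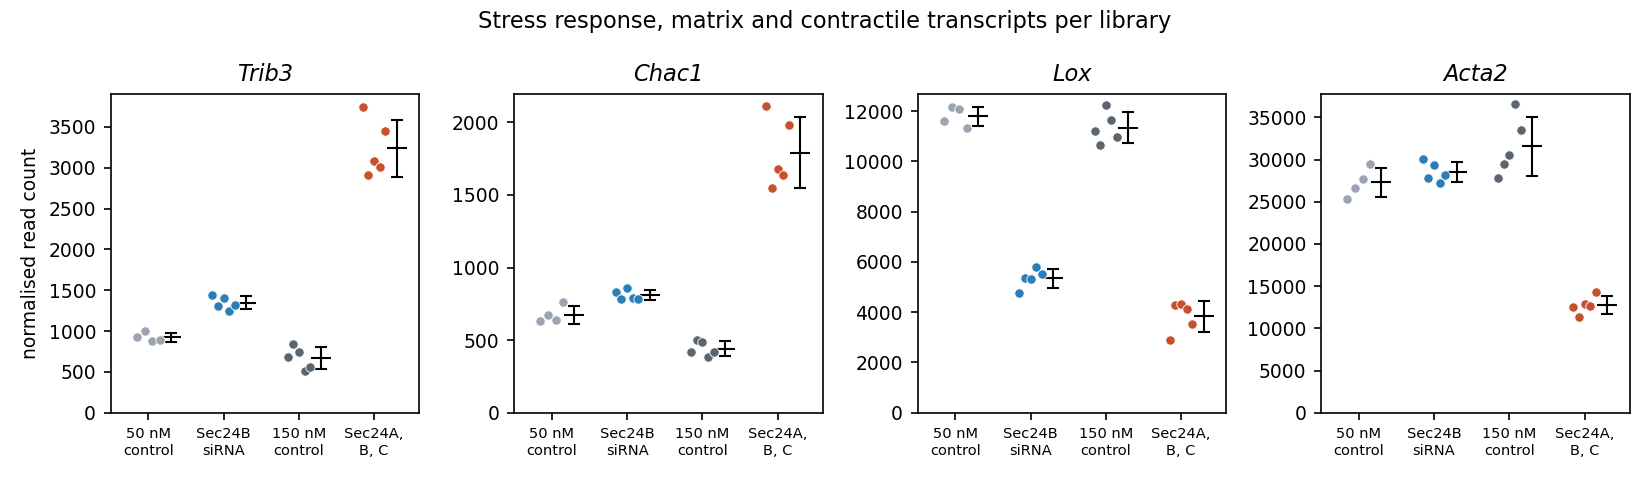
Normalised read counts (vertical axes) of the stress response genes Trib3 and Chac1 and the matrix and contractile genes Lox and Acta2 in each library of the 4 groups, where points are libraries and black bars the mean and SD. The triple knockdown libraries lie above all others for Trib3 and Chac1 and below all others for Acta2; Lox is lower than in the controls in both knockdowns.

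The extracellular matrix program was lower in the triple knockdown. Of 22 collagen chains 17 fell and 0 rose (17 adjusted over the list alone; median -0.51), for example Col3a1 (6380 ± 808 to 3305 ± 151, -0.94 ± 0.07), Col7a1 (-1.10 ± 0.07) and Col12a1 (-1.43 ± 0.13). Of 30 other matrix genes 17 fell and 0 rose (18 adjusted over the list alone; median -0.59), among them Thbs1 (32204 ± 5355 to 11110 ± 1295, -1.53 ± 0.11), Tnc (-1.55 ± 0.11) and Thbs2 (-1.05 ± 0.08), which encode thrombospondins and tenascin C. Camera adjusted p-values were 1.42e-10 and 5.37e-10, and both lists held with an estimated correlation (adjusted p = 0.0219 each). In the list of collagen modification and folding 12 of 28 fell and 3 rose (14 and 3 adjusted over the list alone; median -0.14). Lox fell there from 11341 ± 613 to 3831 ± 609 (-1.58 ± 0.08, adjusted p = 2.95e-13), Loxl2 by 0.74 ± 0.07 and the procollagen protease Bmp1 by 0.67 ± 0.06 on the log2 scale. Contractile genes had 7 of 15 lower and 0 higher (8 adjusted over the list alone; median -0.26), with smooth muscle actin Acta2 at 31567 ± 3496 and 12721 ± 1059 (-1.31 ± 0.08) and non-muscle myosin Myh9 at -0.97 ± 0.10. TGF-beta targets had 7 of 11 lower and 1 higher (the same counts adjusted over the list alone; median -0.26), including the transcription factor Bhlhe40 (-0.78 ± 0.07). The camera adjusted p-values of these 3 lists were 0.00179, 0.000424 and 0.00252 (adjusted p = 0.166, 0.139 and 0.106 with an estimated correlation). The 150 nM control was itself higher than the 50 nM control for contractile genes (median 0.28) and TGF-beta targets (0.19). For contractile genes this is about the size of the fall, although Acta2 in the triple knockdown also lay below every 50 nM library.

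Cell cycle genes also fell in the triple knockdown. All 26 mitosis genes were lower (26 adjusted over the list alone; median -0.54), such as Ccnb1 (2310 ± 77.5 to 1303 ± 238, -0.85 ± 0.09), Top2a (-0.66 ± 0.07) and Aurka (-0.56 ± 0.06). DNA replication genes had 13 of 20 lower and 0 higher (15 adjusted over the list alone; median -0.24), including the ribonucleotide reductase subunit Rrm2 (-0.71 ± 0.05), Mcm4 (-0.60 ± 0.06) and Ccne1 (-0.77 ± 0.09). Apoptosis regulators had 7 of 18 lower and 2 higher (the same counts adjusted over the list alone; median -0.13). The BH3-only killers Bmf (-1.53 ± 0.12) and Bcl2l11 (-0.93 ± 0.08) and the pore former Bak1 (-0.38 ± 0.05), all known to promote cell death, had the smallest adjusted p. Camera adjusted p-values were 4.16e-18, 4.04e-07 and 0.0144, and the 3 lists held with an estimated correlation (adjusted p = 0.0358, 0.0354 and 0.0358).

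Machinery of ER and Golgi transport rose in the triple knockdown by smaller amounts. COPI, tether and SNARE genes had 21 of 27 higher and 0 lower (22 adjusted over the list alone; median 0.27), including the SNAREs Bet1 (0.83 ± 0.09) and Gosr2 (0.50 ± 0.05) and the coat subunit Copb2 (0.47 ± 0.05). COPII coat and exit site genes other than SEC24 had 8 of 17 higher and 1 lower (the same counts adjusted over the list alone; median 0.18), with the GTPase Sar1b at 0.57 ± 0.08, the exit site receptor Mia2 at 0.52 ± 0.06 and the outer coat subunit Sec31a at 0.32 ± 0.05. Genes of ER-associated degradation had 9 of 17 higher and 0 lower (9 adjusted over the list alone; median 0.25), led by Herpud1 (976 ± 102 to 2814 ± 356, 1.52 ± 0.07) and Derl1 (0.67 ± 0.06). Camera adjusted p-values were 3.32e-09, 0.00498 and 0.000137, and the 3 lists held with an estimated correlation (adjusted p = 0.0127, 0.0259 and 0.0358). The translocon list had 10 of 21 higher and 2 lower (11 and 3 adjusted over the list alone; median 0.22; camera adjusted p = 0.00433, adjusted p = 0.136 with an estimated correlation). It holds the channel subunit Sec61a1 at 0.46 ± 0.06 and the signal peptidase subunit Spcs3 at -0.75 ± 0.07. The cargo receptor list had 8 of 22 higher and 1 lower (the same counts adjusted over the list alone; median 0.07), with Yif1a at 0.92 ± 0.09. Its camera adjusted p of 0.0290 (adjusted p = 0.215 with an estimated correlation) became 0.0563 without triple knockdown replicate 1, 0.0779 without replicates 1 and 5, and 0.0838 without triple knockdown replicate 1 and 150 nM scrambled replicate 2.

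ER chaperones of the ATF6 arm did not pass as a list in the triple knockdown, with 3 higher and 6 lower of 17 (4 and 7 adjusted over the list alone; camera adjusted p = 0.636). The chaperone BiP, Hspa5, rose (1.08 ± 0.08, adjusted p = 1.92e-10) while its co-chaperone Dnajb11 fell (-0.66 ± 0.05, adjusted p = 5.39e-10). The ER stress sensor list did not pass either (3 higher and 2 lower of 10, 4 and 2 adjusted over the list alone; camera adjusted p = 0.312), with the transcription factors Xbp1 at 0.77 ± 0.07 (adjusted p = 1.99e-09) and Creb3l1 at -0.97 ± 0.07 (adjusted p = 2.80e-11). The p53 target list showed no shift to either side, with 4 higher and 4 lower of 19 (the same counts adjusted over the list alone; camera adjusted p = 0.940).

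Inflammatory and stress genes went different ways in the triple knockdown. The NF-kB list had 12 of 20 lower and 2 higher (the same counts adjusted over the list alone; median -0.38; camera adjusted p = 0.000409, adjusted p = 0.0358 with an estimated correlation). It holds the chemokines Ccl2 (3055 ± 201 to 1493 ± 106, -1.03 ± 0.06), Ccl7 (-0.96 ± 0.08) and Cxcl1 (-0.81 ± 0.09). NRF2 targets, an antioxidant program, had 10 of 17 higher and 0 lower (12 adjusted over the list alone; median 0.24; camera adjusted p = 0.000369, adjusted p = 0.0565 with an estimated correlation). Among them the heme oxygenase gene Hmox1 rose by 1.19 ± 0.08. Interferon-stimulated genes had 15 of 37 higher and 2 lower (17 and 2 adjusted over the list alone; median 0.27; camera adjusted p = 0.000649, adjusted p = 0.429 with an estimated correlation). Ifi44 (1.17 ± 0.13) and Rsad2 (77.6 ± 10.3 to 175 ± 36.7, 1.15 ± 0.13) rose against 150 nM scrambled siRNA and did not pass against both scrambled groups pooled (log2 fold changes 0.41 and 0.43). Heat shock genes had 8 of 13 lower and 2 higher (9 and 2 adjusted over the list alone; median -0.19; camera adjusted p = 0.00216, adjusted p = 0.0219 with an estimated correlation). Without Hspd1 and Hspe1 these were 8 and 0 of 11 (camera adjusted p = 4.47e-05; adjusted p = 0.00455 with an estimated correlation). The near-identical copies Hspa1a and Hspa1b, which are open to shared reads, were both at -1.08.

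Ribosomal protein genes were higher in the triple knockdown, 32 of 38 with 0 lower (34 adjusted over the list alone; median 0.40; camera adjusted p = 2.11e-10, adjusted p = 0.281 with an estimated correlation). Examples were Rps20 (0.67 ± 0.11), Rpl5 (0.55 ± 0.09) and Rpl10 (0.42 ± 0.06). Their share of the counts was 5.79 ± 1.18% there against 4.31 ± 0.30% with 150 nM scrambled siRNA, and triple knockdown replicate 1 stood highest at 7.67%, followed by replicate 5 at 6.20% (4.91 to 5.09% in replicates 2 to 4). Glycolysis and hypoxia genes had 12 of 21 lower and 2 higher (13 and 3 adjusted over the list alone; median -0.26; camera adjusted p = 0.00265, adjusted p = 0.194 with an estimated correlation). Pgam1 fell (-0.59 ± 0.05), while the stress-responsive Ndrg1 (1.85 ± 0.10) and the growth factor Vegfa (0.81 ± 0.05) rose. In the lysosome and autophagy list 13 of 28 rose and 5 fell (13 and 6 adjusted over the list alone; median 0.12; camera adjusted p = 0.0135, adjusted p = 0.281 with an estimated correlation). The call ended without triple knockdown replicates 1 and 5 (0.0960). The autophagy receptor Sqstm1 rose from 13371 ± 1019 to 33355 ± 4007 (1.31 ± 0.07). Golgi glycosylation genes had 12 of 24 lower and 2 higher (12 and 3 adjusted over the list alone; median -0.22; camera adjusted p = 0.000411, adjusted p = 0.0940 with an estimated correlation). Chst11 stood at -0.90 ± 0.09 there.

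Markers of cell identity fell in part. The endothelial (1 higher and 2 lower of 5), epithelial (0 and 1 of 6) and adipocyte (1 and 0 of 5) lists did not pass. Their counts adjusted over the list alone were the same, and their camera adjusted p-values were 0.861, 0.287 and 0.346. Cartilage and bone markers had 4 of 6 lower and 0 higher (4 adjusted over the list alone; median -0.71; camera adjusted p = 0.00227, adjusted p = 0.0219 with an estimated correlation). They included osteopontin, Spp1 (4114 ± 437 to 1268 ± 363, -1.75 ± 0.15), and the osteoblast regulator Runx2 (-0.96 ± 0.09). Fibroblast markers had 3 of 11 lower and 0 higher (3 adjusted over the list alone; median -0.18; camera adjusted p = 0.00816, adjusted p = 0.0358 with an estimated correlation). These were Pdgfrb (-0.65 ± 0.06), Prrx1 (-0.77 ± 0.07) and Fbln1 (-0.31 ± 0.07). Of 5 macrophage markers 3 were lower and 0 higher (3 adjusted over the list alone; median -0.74; camera adjusted p = 0.0290, adjusted p = 0.0760 with an estimated correlation). Cd14 went from 319 to 189 and Cd68 from 112 to 52.6, and Csf1r (-0.74 ± 0.23) lost its call without triple knockdown replicates 1 and 5 (-0.63). The matrix protease list passed as lower (7 of 14 lower and 1 higher, the same counts adjusted over the list alone; median -0.16; camera adjusted p = 0.0290, adjusted p = 0.173 with an estimated correlation), and its call ended with the stricter filter (0.0616). Its member with the smallest adjusted p, Mmp11, rose (1.18 ± 0.06). The respiratory chain list (median 0.20, 9 of 27 higher and 1 lower, the same counts adjusted over the list alone) passed at 0.0174 (adjusted p = 0.554 with an estimated correlation). It lost its call without 150 nM scrambled replicate 3 (0.0552) or triple knockdown replicate 1 (0.146) or 5 (0.0516), without both of the latter (0.775), and without triple knockdown replicate 1 and 150 nM scrambled replicate 2 (0.0857). The RNA interference list (median -0.15, 4 of 12 lower and 1 higher, the same counts adjusted over the list alone) passed at 0.0421 (adjusted p = 0.429 with an estimated correlation). It lost its call without 150 nM scrambled replicate 1 (0.0631) or 4 (0.0622) or triple knockdown replicate 1 (0.137) or 5 (0.0730), without both of the latter (0.353), without triple knockdown replicate 1 and 150 nM scrambled replicate 2 (0.0857), and with the stricter filter (0.0659).

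**Figure D3:**
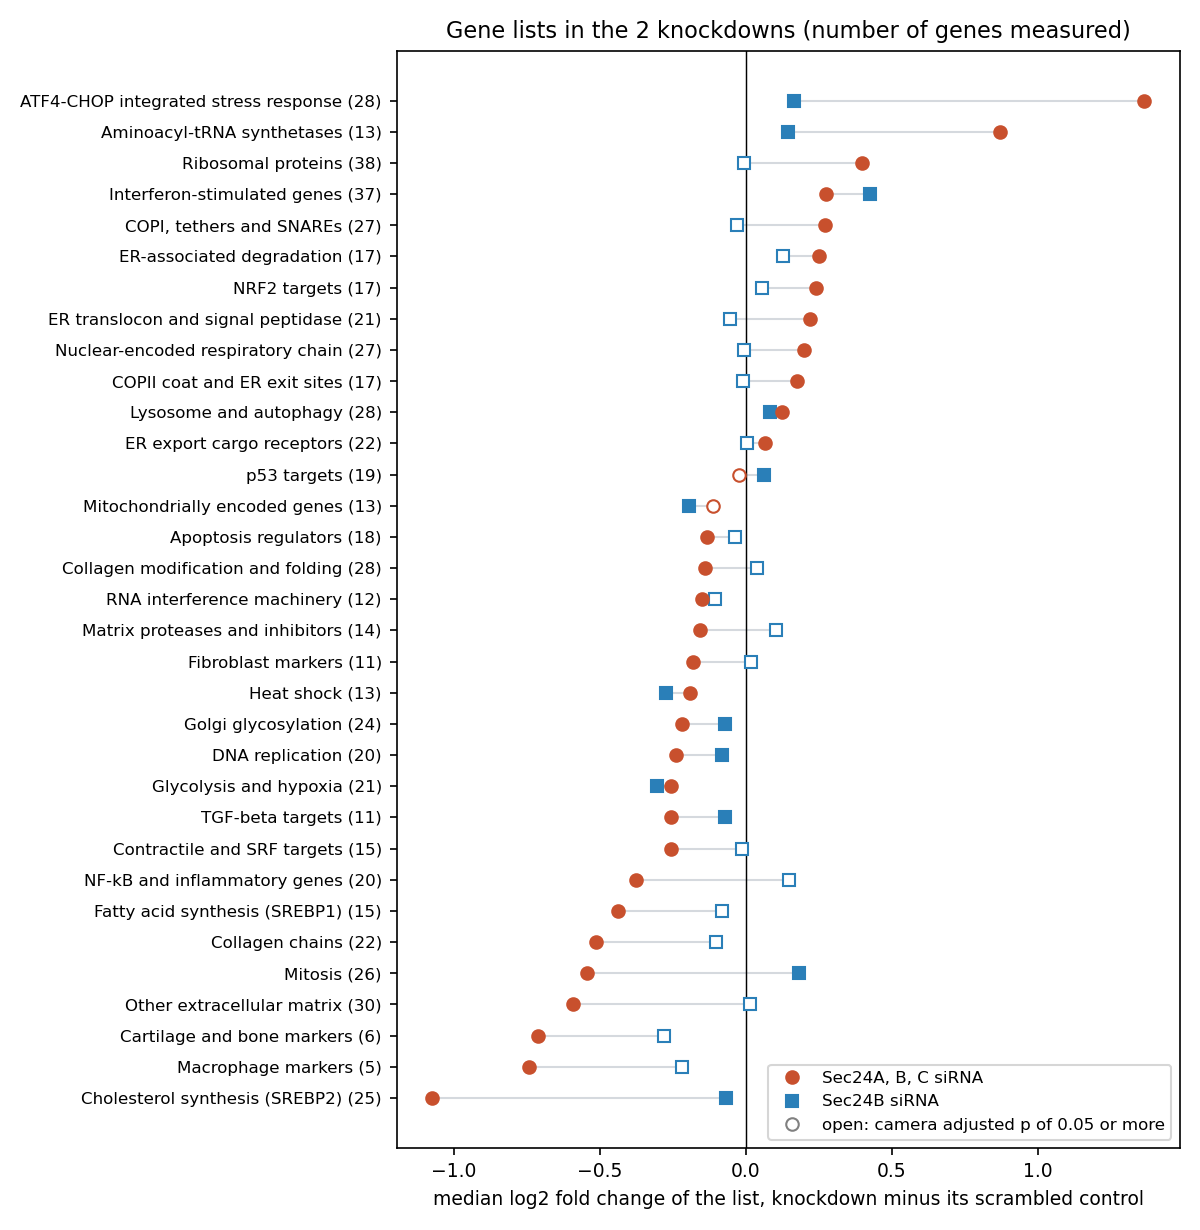
Median log2 fold change (horizontal axis) of each gene list that passed the camera test in at least 1 of the knockdowns, for the triple knockdown against 150 nM scrambled siRNA (circles) and the Sec24B knockdown against 50 nM scrambled siRNA (squares). Open symbols mark lists that did not pass in that comparison, and the ends of the triple knockdown's range are the ATF4-CHOP list at 1.36 and the cholesterol list at -1.08.

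The single genes that follow had the largest changes in the triple knockdown by the rule for named genes. Car6, a secreted carbonic anhydrase, rose from 1.55 ± 1.07 to 69.0 ± 13.2 (log2 fold change 4.89 ± 0.41, adjusted p = 1.22e-09) and Atp2a3, the ER calcium pump SERCA3, from 8.74 ± 3.29 to 171 ± 29.0 (4.20 ± 0.24, adjusted p = 1.04e-12). P2rx3, an ATP-gated ion channel, rose from 13.3 ± 4.75 to 201 ± 32.2 (3.87 ± 0.22, adjusted p = 1.04e-12) and Angptl6, a secreted angiopoietin-like protein, from 23.9 ± 2.65 to 325 ± 102 (3.67 ± 0.20, adjusted p = 6.80e-13). Akr1b7 (4.13 ± 0.49), Sh2d6 (4.08 ± 0.31), Cabp1 (3.99 ± 0.37) and Tenm4 (3.48 ± 0.21) rose from control means of 0.82 to 9.80. Ndnf fell from 437 ± 55.6 to 59.1 ± 15.1 (-2.89 ± 0.14, adjusted p = 3.73e-14). Tns4, a focal adhesion protein, fell from 49.4 ± 9.47 to 7.03 ± 5.18 (-3.06 ± 0.44) and Slco1a6 from 44.2 ± 4.36 to 4.86 ± 2.09 (-3.01 ± 0.28). Mrgprf (-2.51 ± 0.29), Hs3st1 (-2.50 ± 0.40), Kcnj16 (-2.41 ± 0.36), Atp1b2 (-2.41 ± 0.38) and the sterol pathway enzyme Fdps (25.2 ± 6.74 to 4.02 ± 2.77, -2.50 ± 0.30) fell as well. Fdps has processed pseudogenes, and how reads shared with them were counted is not given.

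Over all 19635 genes, 6680 (34.0%) differed between the triple knockdown and 150 nM scrambled siRNA, 3307 higher and 3373 lower. With both scrambled groups pooled as 1 control the count was 6847, of which 5694 were among the 6680 in the same direction. In 4192 of the 6680 genes every knockdown library lay beyond every control library. Chance gives this for 0.794% of unselected genes, which is not comparable with a share among called genes. A log2 fold change of at least 1 was reached by 432 higher and 462 lower genes. Without triple knockdown replicate 1, with the highest ribosomal protein share, and 150 nM scrambled replicate 2, with the fewest reads, the count was 6130. The same omission gave 3802 for the Sec24B knockdown, 2098 for the scrambled doses and 3346 for the difference between the knockdowns. Triple knockdown replicates 1 and 5 lay far from replicates 2 to 4, with a chi-square per degree of freedom of 44.2 to 45.8 and 15.8 to 18.6 against them (2.54 to 3.27 among replicates 2 to 4). Without both, the count was 6041, with 4263 for the Sec24B knockdown, 3325 for the scrambled doses and 3900 for the difference. With only the triple knockdown and 150 nM scrambled libraries in the fit, the triple knockdown count was 5388.

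The comparison of 150 with 50 nM scrambled siRNA asks what separates the controls themselves. Interferon-stimulated genes were lower at 150 nM: 35 of 37 fell and 0 rose (36 and 1 adjusted over the list alone), with a median log2 fold change of -0.98 (camera adjusted p = 4.28e-56; adjusted p = 0.0307 with an estimated correlation). The chemokine Cxcl10 fell from 236 ± 24.4 to 52.3 ± 10.7 (-2.17 ± 0.21, adjusted p = 3.94e-07), the immunity GTPase Iigp1 from 333 ± 30 to 67.6 ± 11.7 (-2.30 ± 0.18, adjusted p = 1.60e-08), and Rsad2 and Oas2 by 1.63 ± 0.14 and 1.51 ± 0.10 on the log2 scale. ATF4 and CHOP targets had 14 of 28 lower and 0 higher (16 adjusted over the list alone; median -0.25), among them Chac1 (-0.62 ± 0.09) and Trib3 (-0.49 ± 0.10). Aminoacyl-tRNA synthetases had 7 of 13 lower and 0 higher (9 adjusted over the list alone; median -0.21). Contractile genes had 4 of 15 higher and 0 lower (11 adjusted over the list alone; median 0.28), and mitosis genes 7 of 26 higher and 0 lower (12 adjusted over the list alone; median 0.20), including Cdc20 (0.46 ± 0.08) and Aurka (0.32 ± 0.06). The camera adjusted p-values of these 4 lists were 2.31e-10, 1.73e-05, 1.20e-07 and 2.26e-05 (adjusted p = 0.0943, 0.234, 0.105 and 0.409 with an estimated correlation).

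**Figure D4:**
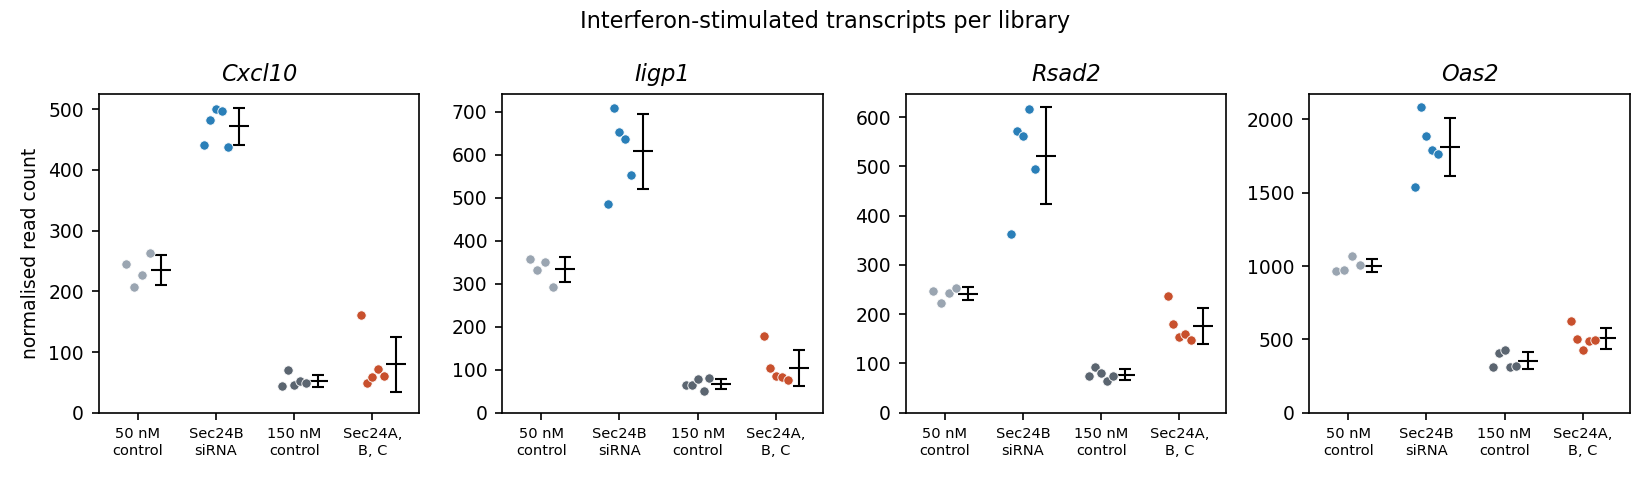
Normalised read counts (vertical axes) of the interferon-stimulated genes Cxcl10, Iigp1, Rsad2 and Oas2 in each library of the 4 groups, where points are libraries and black bars the mean and SD. The Sec24B knockdown libraries are the highest group for all 4 genes and the 150 nM scrambled libraries have the lowest group means. Triple knockdown replicate 1 is the highest of its group for all 4 genes: Cxcl10 (160), Iigp1 (178), Rsad2 (237) and Oas2 (627).

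Further lists that passed between the scrambled doses were higher at 150 nM for NRF2 targets (median 0.16), lysosome genes (0.14) and TGF-beta targets (0.19). They were lower for mitochondrially encoded genes (-0.29), NF-kB genes (-0.17), cholesterol synthesis (-0.09), ER-associated degradation (-0.13) and p53 targets (-0.16). None of these held with an estimated correlation (adjusted p = 0.105, 0.239, 0.187, 0.239, 0.105, 0.427, 0.187 and 0.187). Camera adjusted p-values ran from 5.73e-06 for the mitochondrially encoded genes to 0.00418 for the p53 targets. Calls near the threshold ended without single libraries. Planar cell polarity genes (median 0.16, camera adjusted p = 0.0217) lost theirs without 150 nM replicate 3 (0.0606). ER translocon genes (median -0.10, camera adjusted p = 0.0302) lost theirs without 50 nM replicate 4 (0.0574) or 150 nM replicate 2 (0.0588) or 3 (0.0769). Macrophage markers (median 0.28, camera adjusted p = 0.0443) lost theirs without 50 nM replicate 2 (0.0593) or 3 (0.0782) or 150 nM replicate 1 (0.0582), 2 (0.0588) or 5 (0.0528), without triple knockdown replicates 1 and 5 (0.0586), and without triple knockdown replicate 1 and 150 nM replicate 2 (0.0780). With an estimated correlation these 3 gave adjusted p = 0.357, 0.357 and 0.187. The share of counts from mitochondrial mRNAs was 1.82 ± 0.15% at 50 nM and 1.53 ± 0.13% at 150 nM. Single genes with the largest falls besides those named were Steap4 (9.05 ± 2.89 to 0.846 ± 1.42, -2.67 ± 0.44), a metalloreductase, the acute-phase gene Saa3 (58.9 ± 6.16 to 9.01 ± 3.41, -2.65 ± 0.40) and the mitochondrial tRNA mt-Tt (8.06 ± 3.28 to 0.570 ± 0.847, -2.60 ± 0.61). The largest rises were Pgm5 (to a mean of 16.3, 2.74 ± 0.32), Rhov (2.31 ± 0.39), Hhip (2.25 ± 0.48), Ccbe1 (14.3 ± 6.34 to 61.0 ± 13.5, 2.09 ± 0.36) and the skeletal actin Acta1 (6.36 ± 3.53 to 27.5 ± 8.39, 2.03 ± 0.35). In total 1737 of 19635 genes (8.85%) differed, 932 higher and 805 lower at 150 nM. Of these called genes 1385 were free of overlap between the libraries. Chance gives this for 1.59% of unselected genes, which is not comparable with a share among called genes. The count of 1737 fell to 899 without 50 nM scrambled replicate 1, to 919 without replicate 2 and 1042 without replicate 3 of that group, and to 1137 without 150 nM replicate 3. It rose to 2174 without 50 nM scrambled replicate 4, to 2554 with only the groups compared in the fit and to 3325 without triple knockdown replicates 1 and 5.

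The effects of both knockdowns, each against its own control, were then set against each other. Among genes called in both, 630 were higher in both (248.9 if the calls were independent) and 811 lower in both (238.8), while 167 were higher in the Sec24B and lower in the triple knockdown (253.9) and 97 the reverse (234.1). These comparisons share no library. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.256 over all genes and 0.431 over the 12780 genes with a mean of at least 20. Ndnf, Lox and Slco1a6 were lower in both. The difference between the effects passed for 3107 genes, 1461 more positive and 1646 more negative in the triple knockdown. Of the mitosis genes 11 of 26 passed as higher in the Sec24B knockdown, where the list did not pass with an estimated correlation (adjusted p = 0.491), and 26 of 26 as lower in the triple knockdown. The effects differed for all 26 (26 adjusted over the list alone, median difference -0.81, camera adjusted p = 5.03e-28, and adjusted p = 0.0170 with an estimated correlation). The triple knockdown's control was itself higher in these genes than the Sec24B knockdown's (median 0.20, 7 of 26 higher and 0 lower). That gap did not pass with an estimated correlation (adjusted p = 0.409). It was about the size of the Sec24B rise (median 0.18), while the fall in the triple knockdown was larger (median -0.54). The Sec24B rise and part of the difference thus depend on which scrambled group is subtracted, and the list was not tested against the other. The ATF4 and CHOP targets (26 of 28 more positive, 27 adjusted over the list alone; median 0.99, camera adjusted p = 9.54e-39) and the cholesterol genes (24 of 25 more negative, 24 adjusted over the list alone; median -0.91, camera adjusted p = 1.63e-32) also differed, and both held with an estimated correlation (adjusted p = 0.000396 and 0.00430).

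The authors' own test values, in the deposited table, called 3243 genes for the Sec24B knockdown at an adjusted p of 0.05, 2750 of them also called here in the same direction. They called 6635 for the triple knockdown (6354 also called here in the same direction) and 2195 for the scrambled doses (1664). A further comparison in that table, the triple against the Sec24B knockdown libraries directly, called 6344 genes, 3241 higher and 3103 lower in the triple knockdown. It mixes the knockdowns with the difference between the 50 and 150 nM controls.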

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

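Chosen only after the result was seen were the tests of macrophage markers and of the triple against the Sec24B knockdown for the interferon genes and the tests without triple knockdown replicate 1, and without replicates 1 and 5, for the ribosomal protein genes.

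Interferon-stimulated genes were lower at 150 than at 50 nM scrambled siRNA, with a median log2 fold change of -0.98 and 35 of 37 genes called lower. The shallow library, 150 nM scrambled replicate 2, does not account for it, since the median without it was -1.03 (camera adjusted p = 1.41e-58). Fewer macrophages in the 150 nM libraries are also argued against, since macrophage markers had a median of 0.279 there. The most abundant of the 5 measured, Cd14 and Cd68, went from 250 to 319 and from 51.5 to 112. The triple knockdown libraries were lower than the Sec24B knockdown libraries as well (median -1.19, 36 of 37 genes lower and 1 higher, camera adjusted p = 1.11e-30; adjusted p = 0.0325 with an estimated correlation), which is consistent with a difference between the 50 and 150 nM sets of cultures as a whole. Whether the siRNA amount or the handling of the sets lies behind it stays open, because the design has no set with both amounts. The labels name no sets, which were read from the doses and library names. They also do not say whether the 50 nM of the triple knockdown was each siRNA or the total. If it was the total, a larger siRNA amount would not cover those libraries.

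Ribosomal protein genes were higher in the triple knockdown, with a median log2 fold change of 0.40. Triple knockdown replicate 1, which held the highest share, does not account for it alone: the median without it was 0.277 (camera adjusted p = 2.08e-09). A bias towards short transcripts as the whole of the 0.40 is argued against too, although log2 fold change and transcript length were related over coding genes (Spearman -0.245). Other coding genes matched to them on length (median 995 bases against 969.5) and mean had a median of 0.0345, with a 95% range of -0.122 to 0.185. This range covers only the choice among matched genes, and length is that of the longest annotated transcript. The match used all libraries and was not repeated without replicates 1 and 5. Replicate 5 held the next highest share (6.20%, against 4.91 to 5.09% in replicates 2 to 4). Without replicates 1 and 5 the median was 0.176, with 20 of 38 genes higher and 0 lower (camera adjusted p = 4.00e-06; adjusted p = 0.355 with an estimated correlation). The list thus still passed at a lower median, and what these 2 libraries add cannot be told apart from an effect of the knockdown. With all libraries the list did not pass with an estimated correlation either (adjusted p = 0.281), and no other difference in RNA quality was tested.

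The next pattern lies in 7-base words of 3' UTRs, where siRNAs can act on unintended transcripts through their seed. Genes with GAGTACC in the 3' UTR were lower in the Sec24B knockdown: 148 of 480 were called lower and 26 higher (30.8% lower, against 11.1% of genes without it), and its t of -10.2 was the most negative of 15565 words (most extreme of 100 permutations 5.28). In the triple knockdown its t, adjusted for 3' UTR length, GC content and expression, was -2.42, inside that comparison's limit of 5.62. Without adjustment 39.2% of genes with it were called lower there against 25.6% without it, and 14.6% against 24.5% higher, with a median log2 fold change of -0.11, as in the Sec24B knockdown (-0.11). A seed effect of an siRNA used in both knockdowns is thus neither shown nor excluded. The longest Sec24b transcript holds 2 sites of the word or its reverse complement GGTACTC, and 38.7% of coding genes at least as long hold 1 or more. A match to Sec24b could thus be chance, and the labels do not give the siRNA sequences. AGTACCA, which overlaps GAGTACC, and ATCCTAA were picked after their scores were seen. They had t of -7.24 and -7.51 in the Sec24B knockdown (limit 5.28), and -1.90 and -3.07 in the triple knockdown. A seed effect confined to the Sec24B knockdown was not tested and stays open. For the scrambled siRNA, the most negative word of the dose comparison, GGATTGC, had a t of -3.73 there (limit 4.99) and 2.25 in the triple knockdown, which decides nothing. Positive words, picked after their scores were seen, were CACATCA and ACATCAA, which overlap. They had t of 7.62 and 7.04 in the Sec24B knockdown (limit 5.28). In the triple knockdown they had 3.75 and 4.38, inside the limit of 5.62, and between the doses -1.94 and 0.12. A seed effect of the scrambled siRNA is thus neither shown nor excluded.

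The gene counts were compared with those from other splits of the same libraries, 100 in each case with the real one included. In each comparison only the real split, 1 of 100, gave as many genes. The counts were 2868 in the Sec24B knockdown (highest other 1049), 6680 in the triple knockdown (highest other 1567), 1737 between the scrambled doses (highest other 589) and 3107 for the difference of effects (highest other 1). Splits that mix differing groups widen the spread, which lowers their counts. For the difference of effects, libraries were shuffled within each knockdown and its control. That removes both knockdown effects, so it cannot test whether the effects were equal. Splits also cannot tell whether replicates were separate cultures.

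Single libraries far from the rest of their group were found in 15 of 236 groups of values; chance gives about 1 in 20. Triple knockdown replicate 1 stood above its group for Saa3 (93.3; others 9.77 to 17.8), mt-Tt (15.5; 0 to 3.39), Iigp1 (177.8; 75.4 to 103), Cxcl10 (160.3; 48.9 to 71.7) and Cabp1 (37.9; 19.7 to 22.9). Replicate 2 of that group was low for Rcsd1 (1.09; 3.93 to 5.08). Replicate 5 of that group was low in mitochondrial mRNA share (1.28%; 1.54 to 1.60%) and high for Ptpn7 (4.23; the others from 1.09). Among 150 nM scrambled libraries, replicate 1 stood out for Ankrd7 (1.92; all others 0), replicate 5 for Akr1b7 (4.75; 0 to 1.10), replicate 3 for Rhov (9.91; 5.68 to 6.73) and replicate 2 for Steap4 (3.28; 0 to 0.95). Sec24B replicate 4 was high for P2rx3 (49.3; 25.8 to 32.6), Sec24B replicate 2 for Dthd1 (4.27; 0 to 1.17), and 50 nM scrambled replicate 2 for Flrt3 (9.57; 1.18 to 2.36).

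The knockdown effects differed from each other, by the test of the difference, for 3107 genes, of which 264 were called in opposite directions in the Sec24B and triple knockdowns. The genes most positive in the triple knockdown were Car6 (4.60 ± 0.60), Sh2d6 (4.02 ± 0.45), Akr1b7 (3.82 ± 0.71), Etnk2 (3.18 ± 0.81) and Dthd1 (3.16 ± 0.63), and the most negative Fndc7 (-3.13 ± 0.51), Ptpn7 (-3.07 ± 0.48), Flrt3 (-2.88 ± 0.63), Prelp (-2.78 ± 0.53) and Atp1b2 (-2.60 ± 0.56). Lists that differed, with the median difference, were more positive for ATF4 and CHOP targets (0.990), aminoacyl-tRNA synthetases (0.748), ribosomal proteins (0.410), COPI and SNARE genes (0.274), ER-associated degradation (0.221), ER translocon (0.220), COPII (0.163), cargo receptors (0.140), NRF2 targets (0.114) and the respiratory chain (0.146). They were more negative for cholesterol synthesis (-0.907), mitosis (-0.805), cartilage and bone markers (-0.545), NF-kB genes (-0.504), other matrix (-0.446), collagen chains (-0.440), fibroblast markers (-0.413), fatty acid synthesis (-0.391), matrix proteases (-0.213), contractile genes (-0.191), interferon genes (-0.188), collagen modification (-0.152) and DNA replication (-0.116). With an estimated correlation 11 of these 23 passed. The other 12 were ribosomal proteins (adjusted p = 0.319), ER-associated degradation (0.0503), cargo receptors (0.110), NRF2 targets (0.111), the respiratory chain (0.655), cartilage and bone markers (0.0837), fatty acid synthesis (0.0503), matrix proteases (0.111), contractile genes (0.272), interferon genes (0.606), collagen modification (0.152) and DNA replication (0.319). Single libraries ended 3 calls: cartilage and bone without 50 nM scrambled replicate 3 (adjusted p = 0.0530); DNA replication without 50 nM scrambled replicate 1 (0.0786), 150 nM scrambled replicate 4 (0.0507) or triple knockdown replicate 2 (0.0516) or 3 (0.0593); and the respiratory chain without 50 nM scrambled replicate 4 (0.132), Sec24B replicate 2 (0.0552), 4 (0.0595) or 5 (0.0523), 150 nM scrambled replicate 3 (0.0852) or triple knockdown replicate 1 (0.279) or 5 (0.0877). Without triple knockdown replicates 1 and 5 together the respiratory chain changed direction (0.963), and its call also ended with the stricter filter (0.0526) and without triple knockdown replicate 1 and 150 nM scrambled replicate 2 (0.179).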

How the results depend on the processing

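The runs on recovered reads, limma-voom among them, without triple knockdown replicate 1 and 150 nM scrambled replicate 2, without triple knockdown replicates 1 and 5, and of the heat shock list without its mitochondrial members were added after the data were seen. In the settings examined no gene named as passing changed direction. The other scrambled group as control was fitted for all genes but read out only for the SEC24 transcripts. Reversals of other genes against it were thus not counted, and lists were tested with neither this control nor the pooled controls. Rsad2, called higher in the triple knockdown, had 147 to 237 counts there and 222 to 253 in the 50 nM control. For Oas2 every triple knockdown library lay below every 50 nM library (427 to 627 against 966 to 1066). The same held for Iigp1 (75.4 to 178 against 292 to 359) and Cxcl10 (48.9 to 160 against 207 to 263). Of the lists that passed, only the respiratory chain in the difference of effects changed direction, without triple knockdown replicates 1 and 5 (adjusted p = 0.963). Sec24d, which did not pass, changed sign in the triple knockdown from -0.11 to 0.12 without triple knockdown replicate 1, 0.11 without that library and 150 nM replicate 2, 0.19 without replicates 1 and 5, and 0.01 with the other control. In the Sec24B knockdown it went from 0.07 to -0.06 with the other control, and Sec24c, near 0, also changed sign there (0.04 with quantile normalisation). Over the settings the share of called genes that were higher ran from 49.2 to 72.2% in the Sec24B knockdown, 48.0 to 53.5% in the triple knockdown, 46.0 to 54.8% between the doses and 39.9 to 48.7% in the difference. With an absolute log2 fold change of at least 1 the counts were 313, 894, 250 and 494 for the Sec24B knockdown, the triple knockdown, the scrambled doses and the difference of effects, and Sec24a in the triple knockdown (-0.76) no longer counted, since the setting demands larger changes. With both scrambled groups pooled as 1 control the Sec24B count was 4470; the cause was not tested. Without triple knockdown replicates 1 and 5 the count between the doses was 3325 and Sec24a passed in the Sec24B knockdown (-0.19); there these libraries enter only through the pooled spread. Leaving out 1 replicate gave 2132 to 2537, 6010 to 6635, 899 to 2174 and 2581 to 3518 genes. With only the groups compared in the fit, the counts were 3946 for the Sec24B knockdown, 5388 for the triple knockdown and 2554 for the scrambled doses. Among the doses, the counts without 50 nM scrambled replicates 1, 2 and 3 and 150 nM replicate 3 were 899, 919, 1042 and 1137, with fewer samples. With an estimated correlation 1, 15, 1 and 11 lists passed, in place of 13, 31, 16 and 23. The estimate lay above the fixed 0.01 for most lists, for example 0.525 for interferon genes, which widens the test. It lay below 0.01 for some lists, such as heat shock (-0.00683), COPII (-0.022) and apoptosis genes (-0.0484). With the replicate number as a block the counts were 2654, 6644, 1414 and 3108; the numbers pair nothing, as libraries of a like number correlated at r = -8.84e-05 on average over 27 pairs. On the recovered reads edgeR gave 3184, 6716, 1934 and 3315 genes, of which 2751, 6318, 1661 and 2974 were shared with limma in direction, and DESeq2 gave 3248, 6707, 2178 and 3472. Upper-quartile factors in edgeR gave 3220 genes in the Sec24B knockdown, 64.7% of them higher, against 49.3% with its default factors and 51.5% in the limma fit. Median-of-ratios rescaling moved the median of all genes by at most 7.3e-05 and gave 2868, 6681, 1737 and 3106 genes. The deposited values were already close to that scaling, so this setting could hardly change the results. Quantile normalisation moved the median by at most 0.019. In edgeR, upper-quartile factors put it at 0.04 in the Sec24B knockdown (-0.0043 with default factors, 0.01 in the limma fit). Over the settings, 4918 values of named genes kept side and direction, 117 fell short of the threshold and 14 passed it. Of these 117, 95 came from the minimum absolute log2 fold change of 1, which drops smaller changes by its rule. For lists 1469 kept both and 117 fell short, 55 of them with the estimated correlation. With the fry test in place of camera, calls ended for cholesterol synthesis (0.0600) and mitochondrially encoded genes (0.0513) in the Sec24B knockdown, the respiratory chain (0.120) in the triple knockdown, cholesterol synthesis (0.0651) and mitosis (0.0620) between the doses, and interferon genes (0.306) and the respiratory chain (0.356) in the difference. Depth limits genes with means of a few counts, where 1 read is about 1 normalised count.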

Other observations

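The words named here were picked after their scores were seen; the search itself was planned.

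An AU-rich word in 3' UTRs marked genes that were lower in both knockdowns. TATTTAT, of the kind that mRNA-destabilising proteins bind, had the most negative t of 15565 words in the triple knockdown (-8.35, most extreme of 100 permutations 5.62). Its t was -9.28 in the Sec24B knockdown (most extreme 5.28). These scores are adjusted for 3' UTR length, GC content and expression; the shares that follow are not. Of 3290 genes with it, 32.7% were called lower in the triple knockdown against 23.2% of genes without it, and 17.0% against 9.73% in the Sec24B knockdown. Between the scrambled doses its t was 4.26, inside the limit of 4.99, but other A/T-rich words lay beyond that limit on the positive side: TTTTAAT (6.52), TTTTTTT (6.42), TTTTTTA (6.20) and TATATAT (5.07). The controls thus also differed in genes with A/T-rich words, and they are part of each knockdown comparison. Genes with ATCCTAA (897 genes, t -7.51) were called lower in 21.5% of cases in the Sec24B knockdown, against 11.2% of those without it. Genes are not independent replicates.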
